A study of Mus musculus with 36 samples.

How the data were processed

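The samples were soleus muscles of young and old male mice in 6 groups (control, unloading and reloading at each age), with 36 libraries and 1 mouse per library. Per the labels, ribosomal RNA was depleted from total RNA, and single-end reads of 50 bases were sequenced on 1 flow cell of an Illumina instrument; the labels name both a stranded total RNA kit and another RNA kit, and whether strand was used in counting is not given in the sources used here. The submitters' processing notes name TopHat2 2.0.1, TopHat, Partek 6.6 and DESeq with the mm10 genome, without their role or order.

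The deposited table has 31668 transcript rows with, per the file headers, a read column and an RPKM column for each library. The read columns hold estimated counts (expected counts) that the authors divided among the transcripts of a gene: 55.68% of the transcript values and 94.94% of the gene sums were whole to within 0.01 reads. The RPKM columns hold, per the file headers, reads per kilobase of transcript and per M reads of the library; the library total they imply was larger than the sum of the read column. RPKM values were used only for that check. A spreadsheet had turned 56 symbols into dates, from which 25 genes were restored by their transcript identifiers, so that 21154 symbols became 21156 genes; 7 symbols lay on more than 1 chromosome and were kept as deposited. The table holds 0 of the mitochondrially encoded genes.

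Reads were summed over the transcripts of each gene and rounded. Library totals ran from 32.0 to 37.9 M reads. Genes with too few reads were removed with filterByExpr, leaving 15031. Libraries were scaled with TMM, and 1 model with a coefficient for each of the 6 groups (30 residual degrees of freedom) was fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest; limma 3.58.1, R 4.3.3). The common biological coefficient of variation was 0.149. There were 12 comparisons, 3 of them differences between the ages in a response, and p values were adjusted with the Benjamini-Hochberg method over the genes tested within each, at 0.05. The SE of a log2 fold change is its size over the square root of its F statistic. CPM values use the TMM-scaled totals. No covariate was used, since the labels give no batch, and the mouse numbers did not pair libraries across groups. Genes with near-identical copies, such as those of alpha globin, of ribosomal proteins and of the myosin heavy chain family, can share reads of this length, so their values are less certain. Within groups 105 pairs of libraries were compared (lowest chi-square per degree of freedom 8.93), and none was a duplicate of another.

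Before the data were examined, 40 gene lists and the rule for naming genes were fixed. For each comparison the rule takes the 6 largest rises and 6 largest falls among called genes with a mean of at least 8 CPM, leaving out predicted genes (for differences between the ages, the 8 smallest adjusted p), then up to 4 members of each called list by adjusted p, and 22 tracked genes whatever their result; where fewer are printed, they are the first in that order, apart from a few genes that are not reported here. The 39 lists with a gene in the table were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Between 8 and 23 lists were called per comparison; with an estimated correlation 1 was called in 4 comparisons (the mitochondrial ribosome for unloading in young mice, and autophagy and mitophagy for both reloading comparisons in young mice and for reloading after unloading in old mice) and 0 in the other 8. No called list had a median, mean and test that differed in sign. Library measures were compared with exact two-sided permutation tests, 45 in all.

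Alternatives fixed beforehand were DESeq2 1.42.0 size factors and its Wald test, no filter or a stricter one (5 CPM in at least 4 libraries), fitting only the groups compared, a block for the mouse number, the transcript with the highest mean in place of the sum, and each library left out in turn. Alternatives added after the data were seen left out the 6 libraries with Alb above 20 CPM, or kept only the controls numbered 1 to 6. Regroupings of the libraries were drawn 90 times per comparison, the real grouping included, to keep the running time short, with repeats and mirror images counted once, at the highest of their counts. A comparison with a real count of 0 was left open, since every grouping calls at least 0 genes, a rule added after the data were seen. A list of 22 liver genes and a list of 12 epithelial genes served the tests of the closing section.

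The fit was tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. It recovered 80 and 95 of them for unloading in young mice (5 false calls among 14913 genes run), 90 and 99 for unloading in old mice (10 false calls), 88 and 99 for age in controls (9), 69 and 96 for reloading in old mice (13), 49 and 82 for the difference between the ages in unloading (3) and 30 and 81 for that in reloading (5), with 0 wrong signs. A list of 30 genes raised 1.3-fold was called in each of the 6 simulations, and 0 of 38 lists of unchanged genes were. The simulated genes varied independently of each other, so this cannot show how often lists of correlated genes are called falsely. Genes of like level were given the same spread, and no library stood apart from its group. Recovery in the real data may therefore be lower.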

Results

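RNA was sequenced from the soleus, a postural calf muscle rich in slow fibres, of 36 male C57BL/6J mice, with 1 mouse per library. Young mice were 6 months old and old mice were 22 to 24 months old. At each age some mice served as controls (9 young and 9 old), some had their hind limbs lifted off the ground for 10 days (unloading; 4 young and 6 old), and some were unloaded for 10 days and then bore weight again for 3 days (reloading; 4 young and 4 old). The libraries held 32.0 to 37.9 M reads assigned to genes. Of 21156 genes in the table, 15031 had enough reads to be tested. Changes are log2 fold changes ± SE, levels are counts-per-million values (CPM) given as mean ± SD, and positions are on mm10. A gene was called when its adjusted p (edgeR quasi-likelihood F test, Benjamini-Hochberg over the genes tested) was under 0.05.

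Ttn, which encodes the giant sarcomere protein titin, alone took 23.4% of the reads of young controls and 25.7% of those of old controls (exact two-sided permutation p = 4.11e-05, Benjamini-Hochberg p = 0.00185 over 45 tests of library measures, n = 9 and 9). Malat1, an abundant nuclear RNA, took 1.01% of the reads of young controls and 1.52% of those of young reloaded mice, and 1.02% and 1.61% in the old mice (each exact two-sided permutation p = 0.0014, Benjamini-Hochberg p = 0.00788). Some libraries stood apart from their group. Alb, the gene of the liver plasma protein albumin (chromosome 5, 90460870 to 90476603), was above 20 CPM in 6 libraries: 1740 CPM in old reloading replicate 2, 154 in old reloading replicate 4, 72.5 and 29.8 in young reloading replicates 1 and 2, 39.6 in young unloading replicate 2 and 36.2 in old unloading replicate 6. The 18 genes of the neuromuscular junction and denervation list averaged 4.26 ± 0.77 (SD of log2 CPM) over the 9 old controls and 3.46 ± 0.14 over the 9 young controls.

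**Figure D1:**
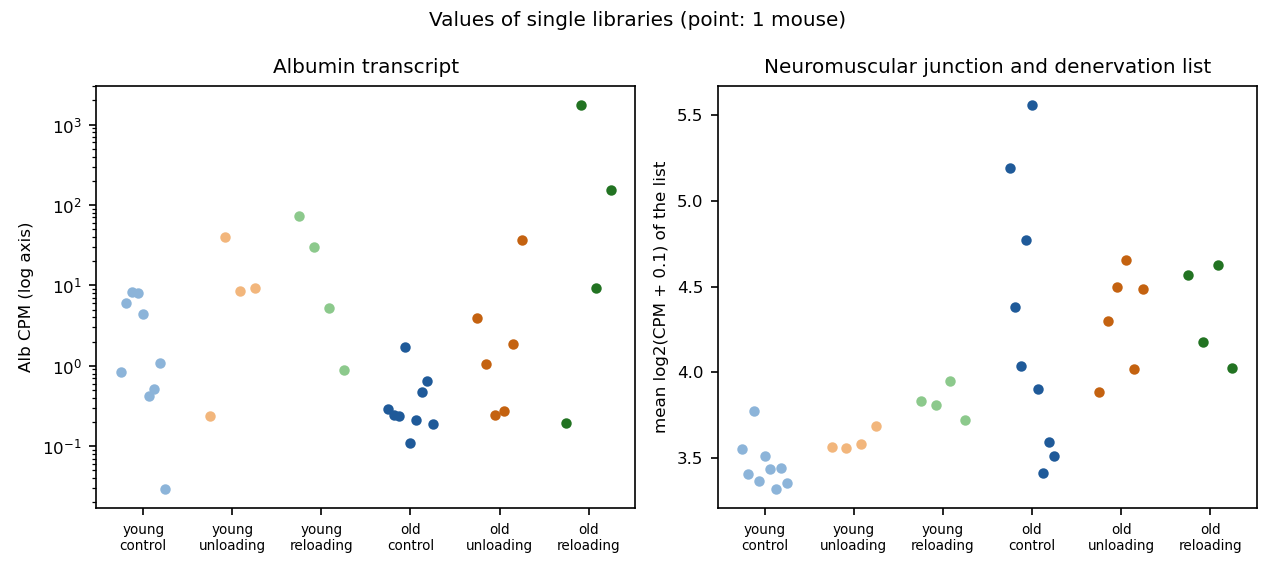
Each point is 1 library, by group; a first panel has Alb in CPM on a log axis and the other the mean log2(CPM + 0.1) of the neuromuscular junction and denervation list. Alb reached 1740 CPM in old reloading replicate 2, and the list mean spread more over the 9 old controls (SD 0.77) than over the 9 young controls (SD 0.14).

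**Figure D2:**
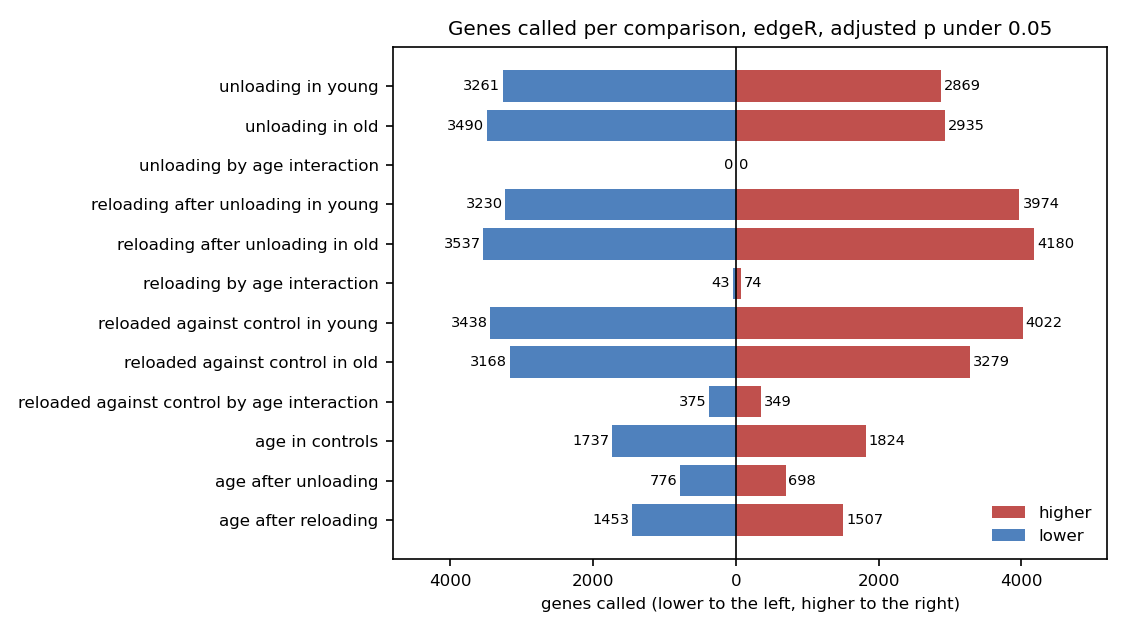
Bars give the number of genes called higher (right of 0) and lower (left of 0) in each comparison of the 6 groups. The counts ran from 0 for the dependence of unloading on age to 7717 for reloading in old mice.

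What unloading did to the young soleus was read from 4 unloaded mice against 9 controls. Myh1, the myosin heavy chain of fast IIx fibres (chromosome 11, 67200114 to 67224576), rose by 2.44 ± 0.35 from 6396 ± 1537 to 34760 ± 8096 CPM, whereas Myh2, the IIa heavy chain, fell by 1.91 ± 0.25 from 15050 ± 1107 to 4020 ± 1119 CPM. Other large rises were those of Inmt, a methyltransferase (1.99 ± 0.30), Arrdc2, an arrestin-domain protein (1.95 ± 0.38), the fatty acid synthase gene Fasn (1.85 ± 0.41), the muscle myosin light chain kinase gene Mylk2 (1.80 ± 0.17) and the fatty acid desaturase gene Scd1 (1.75 ± 0.38). Among called genes with a mean of at least 8 CPM, leaving out predicted genes, the fatty acid-binding protein gene Fabp3 fell most (-2.84 ± 0.30). The ketone body enzyme gene Bdh1 (-2.79 ± 0.26) and Nmrk2, a kinase of NAD synthesis (-2.74 ± 0.49), followed. The transferrin receptor gene Tfrc (-2.29 ± 0.39) and the mitochondrial creatine kinase gene Ckmt2 (-2.21 ± 0.16) also fell deeply. Ppargc1a, a coactivator of mitochondrial gene expression, fell by 1.74 ± 0.44. The ubiquitin ligase gene Fbxo32 rose by 0.54 ± 0.15, while Trim63, the other classical atrophy ligase gene, had a value of -0.25 ± 0.23 (adjusted p = 0.414) and the myostatin gene Mstn 0.37 ± 0.34 (adjusted p = 0.41). The slow heavy chain gene Myh7 had a value of -0.04 ± 0.14 (adjusted p = 0.863).

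Genes of mitochondria, matrix and protein folding fell together in the unloaded young muscle. Of 79 nuclear genes for subunits of oxidative phosphorylation, 75 fell and 4 were not called (76 fell when adjusted over the list alone). The camera adjusted p was 9.5e-54 (adjusted p = 0.158 with an estimated correlation). Ndufs8 fell by 1.06 ± 0.09 and Cycs, which encodes cytochrome c, fell by 1.37 ± 0.11. Of 77 mitochondrial ribosome genes, 69 fell (70 adjusted over the list alone), with Mrpl54 at -0.65 ± 0.06 and Mrpl4 at -0.78 ± 0.07, and this call held with an estimated correlation (camera adjusted p = 1.44e-33, then 0.0466). Of 24 genes of fatty acid oxidation 22 fell (22 adjusted over the list alone, camera adjusted p = 2.19e-15; adjusted p = 0.308 with an estimated correlation). Hadhb fell by 1.32 ± 0.14. Of 34 collagen and matrix genes 24 fell and 10 were not called (24 adjusted over the list alone, camera adjusted p = 7.15e-06; adjusted p = 0.547 with an estimated correlation). Col15a1 (-1.26 ± 0.16) and the type I collagen gene Col1a1 (-2.06 ± 0.32) were among them. Of 18 heat shock and chaperone genes 13 fell (14 adjusted over the list alone, camera adjusted p = 1.95e-05; adjusted p = 0.405 with an estimated correlation). Hspa8 (-1.03 ± 0.13) and Hsph1 (-1.47 ± 0.21) were among them. Of 19 genes of the atrophy programme 8 rose, none fell and 11 were not called (8 rose adjusted over the list alone, camera adjusted p = 0.0138; adjusted p = 0.547 with an estimated correlation). Nedd4 (0.29 ± 0.05) and Fbxo31 (0.75 ± 0.14) were among them. Of 16 circadian genes 11 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.000501; adjusted p = 0.308 with an estimated correlation). Cry2 had a value of 1.11 ± 0.11 and Per1 had 1.47 ± 0.24. In all, 6130 genes were called, 2869 higher and 3261 lower, and 595 of them changed at least 2-fold.

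In the old soleus the same question was put to 6 unloaded mice and 9 controls. Myh1 rose by 2.44 ± 0.33 (4023 ± 2387 to 21770 ± 8431 CPM) and Myh2 fell by 1.08 ± 0.20; Arrdc2 rose by 2.45 ± 0.34, and Chac1, which degrades glutathione, by 2.31 ± 0.41. Nmrk2 fell by 4.28 ± 0.44, Fabp3 by 2.54 ± 0.25, Pln, the phospholamban gene that restrains the slow calcium pump, had a value of -2.52 ± 0.33, and Otud1, a deubiquitinase gene, of -2.31 ± 0.49. Fbxo32 rose by 0.50 ± 0.13, Col1a1 fell by 1.66 ± 0.27 and Ppargc1a fell by 1.56 ± 0.37, while Trim63 had a value of 0.14 ± 0.20 (adjusted p = 0.589). The fastest heavy chain gene Myh4 rose by 3.04 ± 0.83, from 136.4 ± 232.6 to 1120 ± 1179 CPM, so its spread was as wide as its mean. Among called genes with a mean of at least 8 CPM, leaving out predicted genes, the liver genes Apob and Alb had the highest values (4.74 ± 1.73 and 3.98 ± 1.41). Both calls ended without old unloading replicate 6 (adjusted p = 0.594 and 0.448).

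In the unloaded old muscle 74 of 79 oxidative phosphorylation genes fell and 1 rose (74 and 1 adjusted over the list alone, camera adjusted p = 3.13e-36; adjusted p = 0.349 with an estimated correlation). Cycs had a value of -1.10 ± 0.10. Of 77 mitochondrial ribosome genes 66 fell and 1 rose (69 and 1 adjusted over the list alone, camera adjusted p = 7.64e-28; adjusted p = 0.109 with an estimated correlation). Mrpl53 had a value of -0.45 ± 0.04. Of 19 atrophy genes 12 rose (13 adjusted over the list alone, camera adjusted p = 3.37e-05; adjusted p = 0.349 with an estimated correlation). Nedd4 (0.32 ± 0.04), Fbxo31 (0.94 ± 0.13) and Ddit4, an inhibitor of growth signalling (1.67 ± 0.24) were among them. Of 23 macrophage genes 12 rose and 11 were not called (12 adjusted over the list alone, camera adjusted p = 0.00201; adjusted p = 0.734 with an estimated correlation). Cd163 (0.80 ± 0.14) and Gpnmb (0.89 ± 0.18) were among them. Of 12 antigen presentation genes 6 rose (6 adjusted over the list alone, camera adjusted p = 0.00437; adjusted p = 0.575 with an estimated correlation). H2-Ab1 had a value of 1.07 ± 0.18. Of 20 genes of the unfolded protein response 17 fell and 1 rose (18 and 1 adjusted over the list alone, camera adjusted p = 4.15e-06; adjusted p = 0.429 with an estimated correlation). Hyou1 had a value of -0.61 ± 0.08 and Hspa5, the chaperone BiP, had -1.23 ± 0.17. Altogether 6425 genes were called, 2935 higher and 3490 lower, of which 446 changed at least 2-fold.

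Whether the response to unloading depended on age was tested by the difference between the responses. With edgeR 0 of 15031 genes were called (smallest adjusted p = 0.0696; 1487 genes had an unadjusted p under 0.05), and DESeq2 called 8. With only the controls numbered 1 to 6 at each age, a setting added after the data were seen, edgeR called 59. Over genes, the changes of young and old mice correlated at r = 0.735 (Spearman rho 0.759). Genes are not independent replicates. The comparisons share no library, but they share 1 fit and its estimate of the spread of each gene. Expected numbers here and for reloading assume independent calls, so they may be too low. Of 4568 genes called at both ages, 2028 rose in both (560.2 expected) and 2539 fell in both (757.2 expected). The remaining gene, Catsper2, which encodes a sperm ion channel protein, was lower in young (-0.24 ± 0.09) and higher in old mice (0.20 ± 0.08; difference adjusted p = 0.23), and was chosen after its values were seen. Among the lists, macrophage genes had a median difference of 0.66 towards old mice, with 0 of 23 called and 8 higher adjusted over the list alone (camera adjusted p = 2.94e-11; adjusted p = 0.58 with an estimated correlation), and erythroid genes a median of -1.02, with 0 of 9 called and 8 lower adjusted over the list alone (camera adjusted p = 4.97e-07; adjusted p = 0.58 with an estimated correlation). The oxidative phosphorylation genes had a median of 0.15, with 0 of 79 called and 0 adjusted over the list alone (camera adjusted p = 7.19e-18; adjusted p = 0.661 with an estimated correlation).

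**Figure D3:**
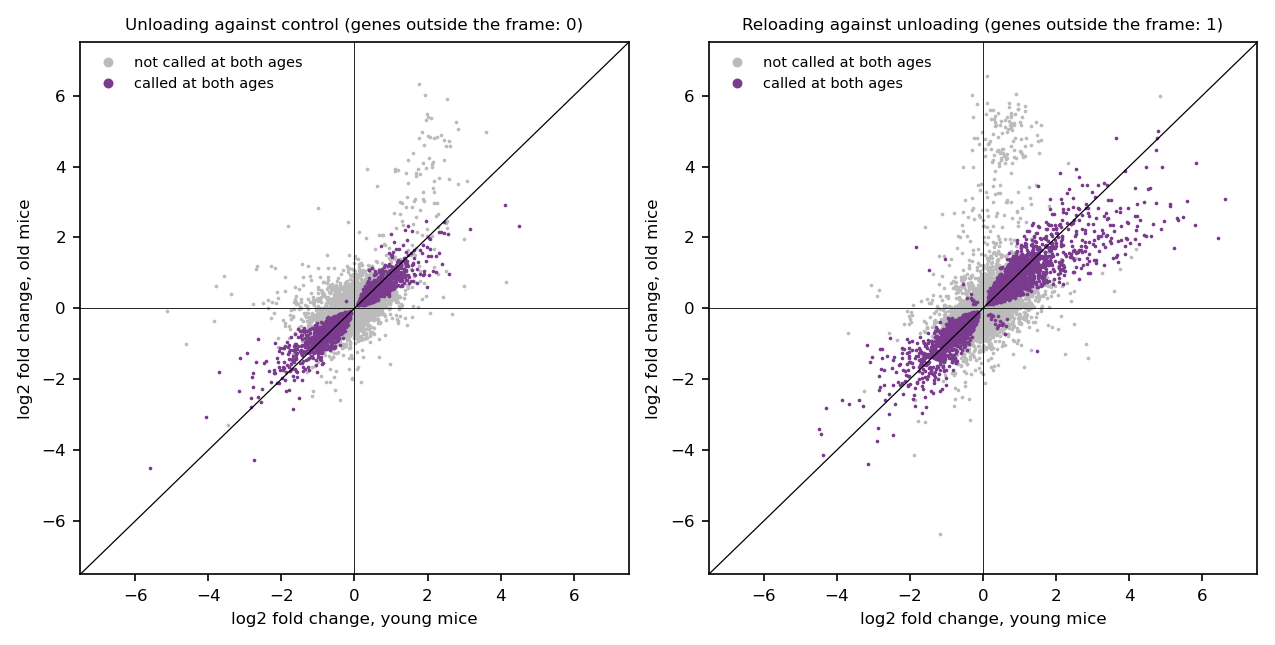
Each point is 1 gene, with its log2 fold change in young mice on the horizontal axis and in old mice on the vertical axis, for unloading and for reloading; coloured points were called at both ages. The changes went together across genes, with r = 0.735 for unloading and 0.68 for reloading.

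What returning weight to the muscle did in young mice was read from 4 reloaded against 4 unloaded mice. Tnc, the matrix protein tenascin C (chromosome 4, 63959785 to 64047016), rose by 4.47 ± 0.55, and Ankrd1, a stretch-responsive sarcomere protein, by 4.22 ± 0.59 from 7.19 ± 1.32 to 134.4 ± 92.7 CPM. The myosin light chain gene Myl6b rose by 4.16 ± 0.45, the myosin-binding protein gene Mybph by 3.88 ± 0.71 and the Z-disc gene Csrp3 by 3.75 ± 0.37. Chac1 fell by 4.38 ± 0.66, Dkk2, a secreted modulator of Wnt signalling, by 3.15 ± 0.29 and Klhl33 by 2.90 ± 0.29. The macrophage gene Cd68 rose by 3.39 ± 0.35 and the proliferation marker Mki67 by 4.96 ± 0.59. Myh1 fell by 2.11 ± 0.45 and Myh2 rose by 2.15 ± 0.28. Fbxo32 fell by 2.21 ± 0.18 and Trim63 by 1.53 ± 0.27. Myog, a transcription factor of muscle differentiation, rose by 1.96 ± 0.63 and the embryonic heavy chain gene Myh3 by 2.83 ± 0.57, while the satellite cell gene Pax7 had a value of 0.24 ± 0.23 (adjusted p = 0.423). Reloading replicate 2 stood apart, with Myog at 4.54 CPM (11.1 to 20.3 in the other 3; 2.79 to 4 in unloaded mice), Ankrd1 at 29.5 CPM (93.1 to 242) and a chi-square per degree of freedom of 83 to 98 with the other 3, against 18.3 to 19.8 among them. The cause was not tested, and no named call of this comparison ended without it.

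Of 34 cell cycle genes 28 rose and 6 were not called in the young reloaded muscle (29 rose adjusted over the list alone, camera adjusted p = 6.11e-12; adjusted p = 0.36 with an estimated correlation). Mcm6 had a value of 2.00 ± 0.16 and Aurkb had 5.79 ± 0.63. Of 34 collagen and matrix genes 26 rose and 1 fell (26 and 2 adjusted over the list alone, camera adjusted p = 1.65e-09; adjusted p = 0.554 with an estimated correlation). Col4a2 had a value of 1.09 ± 0.11. Of 23 macrophage genes 20 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 0.00106; adjusted p = 0.832 with an estimated correlation). Of 18 heat shock genes 13 rose (14 adjusted over the list alone, camera adjusted p = 1.8e-07; adjusted p = 0.36 with an estimated correlation). Hspb7 (2.02 ± 0.17) and Cryab (2.53 ± 0.24) were among them. Of 21 genes of autophagy and mitophagy 15 fell and 3 rose (15 and 3 adjusted over the list alone), with Pink1, which marks damaged mitochondria, at -1.09 ± 0.09 and Map1lc3b at -1.27 ± 0.11, and this call held with an estimated correlation (camera adjusted p = 3.07e-06, then 0.000999). Of 19 atrophy genes 11 fell (11 adjusted over the list alone, camera adjusted p = 3.62e-05; adjusted p = 0.36 with an estimated correlation). Reloading called 7204 genes in young mice, 3974 higher and 3230 lower, with 1330 changed at least 2-fold. Alb exceeded 20 CPM in 2 of the 4 young reloaded libraries and 1 of the 4 young unloaded libraries.

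In old mice 4 reloaded were compared with 6 unloaded mice. Nmrk2 rose by 4.80 ± 0.48, Tnc by 3.98 ± 0.45, Mybph by 3.88 ± 0.58 and Postn, the matrix protein periostin, by 3.69 ± 0.40. Dkk2 fell by 4.40 ± 0.31, Chac1 by 4.15 ± 0.64, Klhl33 by 3.74 ± 0.30 and Arrdc2 by 3.57 ± 0.50. Cd68 rose by 3.49 ± 0.29 (3.58 ± 0.69 to 40.2 ± 18.1 CPM), Mki67 by 2.45 ± 0.45, Ankrd1 by 2.94 ± 0.47, Col1a1 by 3.12 ± 0.32 and Col3a1 by 3.37 ± 0.32, and Fbxo32 fell by 2.11 ± 0.18. Alb and Apob had the highest values among called genes with a mean of at least 8 CPM, leaving out predicted genes (6.04 ± 1.31 and 5.34 ± 1.18). Without the 6 libraries above 20 CPM of Alb, an omission chosen after the data were seen, their adjusted p was 0.251 and 0.399. The same omission, which leaves 2 reloaded libraries at each age, ended the calls of Myh4 (-4.14 ± 1.22; adjusted p = 0.0885) and of the fast myosin-binding protein gene Mybpc2 (-3.22 ± 0.81; adjusted p = 0.06).

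Collagen and matrix genes rose in the old reloaded muscle in 26 of 34 cases and fell in 1 (27 and 1 adjusted over the list alone, camera adjusted p = 2.14e-14; adjusted p = 0.295 with an estimated correlation). Col6a3 had a value of 1.76 ± 0.16. Of 34 cell cycle genes 25 rose and 2 fell (25 and 2 adjusted over the list alone, camera adjusted p = 5.36e-05; adjusted p = 0.803 with an estimated correlation). Mcm6 rose by 2.12 ± 0.14. Of 18 heat shock genes 17 rose (17 adjusted over the list alone, camera adjusted p = 4.67e-09; adjusted p = 0.206 with an estimated correlation). Hspb1 rose by 2.62 ± 0.24. Of 79 cytosolic ribosomal protein genes, many of which share reads with near-identical copies, 61 rose (63 rose and 1 fell adjusted over the list alone, camera adjusted p = 9.39e-10; adjusted p = 0.803 with an estimated correlation). Rplp0 rose by 0.67 ± 0.05. Of 21 autophagy genes 14 fell and 2 rose (14 and 2 adjusted over the list alone), a call that held with an estimated correlation (camera adjusted p = 3.67e-05, then 0.00462). Of 19 atrophy genes 16 fell (16 adjusted over the list alone, camera adjusted p = 2.73e-08; adjusted p = 0.185 with an estimated correlation). Fbxo31 fell by 1.72 ± 0.17. Of 7717 genes called, 4180 were higher and 3537 lower, and 1427 changed at least 2-fold.

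The response to reloading differed between the ages in 117 genes, 74 with a more positive and 43 with a more negative change in old mice. Of 10 named calls 3 (Ldhd, Myh14 and Suox) held in every alternative run. The smallest adjusted p (0.0137) was shared by Ldhd, a lactate dehydrogenase of mitochondria (-1.08 ± 0.18), the citrate lyase gene Acly (1.23 ± 0.22), the nonmuscle myosin gene Myh14 (0.78 ± 0.14), the microtubule adaptor gene Hook3 (0.42 ± 0.08) and the sulfite oxidase gene Suox (0.78 ± 0.15). Of these, the calls of Acly and Hook3 ended without the 6 libraries above 20 CPM of Alb (adjusted p = 0.105 and 0.112), under which 55 genes were called, and when only the 4 groups compared were fitted (adjusted p = 0.0744 and 0.0748), under which 17 were called. Cell cycle genes had a median difference of -1.13, with 1 of 34 called lower, Aurkb (-3.45 ± 0.84; adjusted p = 0.0383, and 0.18 without those 6 libraries), and 16 lower adjusted over the list alone (camera adjusted p = 3.19e-12; adjusted p = 0.806 with an estimated correlation). The value of Mki67 was -2.51 ± 0.73 (adjusted p = 0.0813). Without each of 9 libraries in turn the count moved by over 1.5 times, from 47 without old reloading replicate 4 to 258 without young reloading replicate 1. Over genes, reloading in young and old mice correlated at r = 0.68 (rho 0.768). Of 5381 genes called at both ages 2861 rose in both (1105.1 expected) and 2484 fell in both (760.1 expected).

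How the changes of reloading lined up with those of unloading was read across ages, where no library is shared. Of 3829 genes called both for unloading in old and for reloading in young mice, 86.9% went in opposite directions (r = -0.267, rho -0.384, over genes). Of 3862 genes called for unloading in young and reloading in old mice 88.2% did (r = -0.173, rho -0.413).

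**Figure D4:**
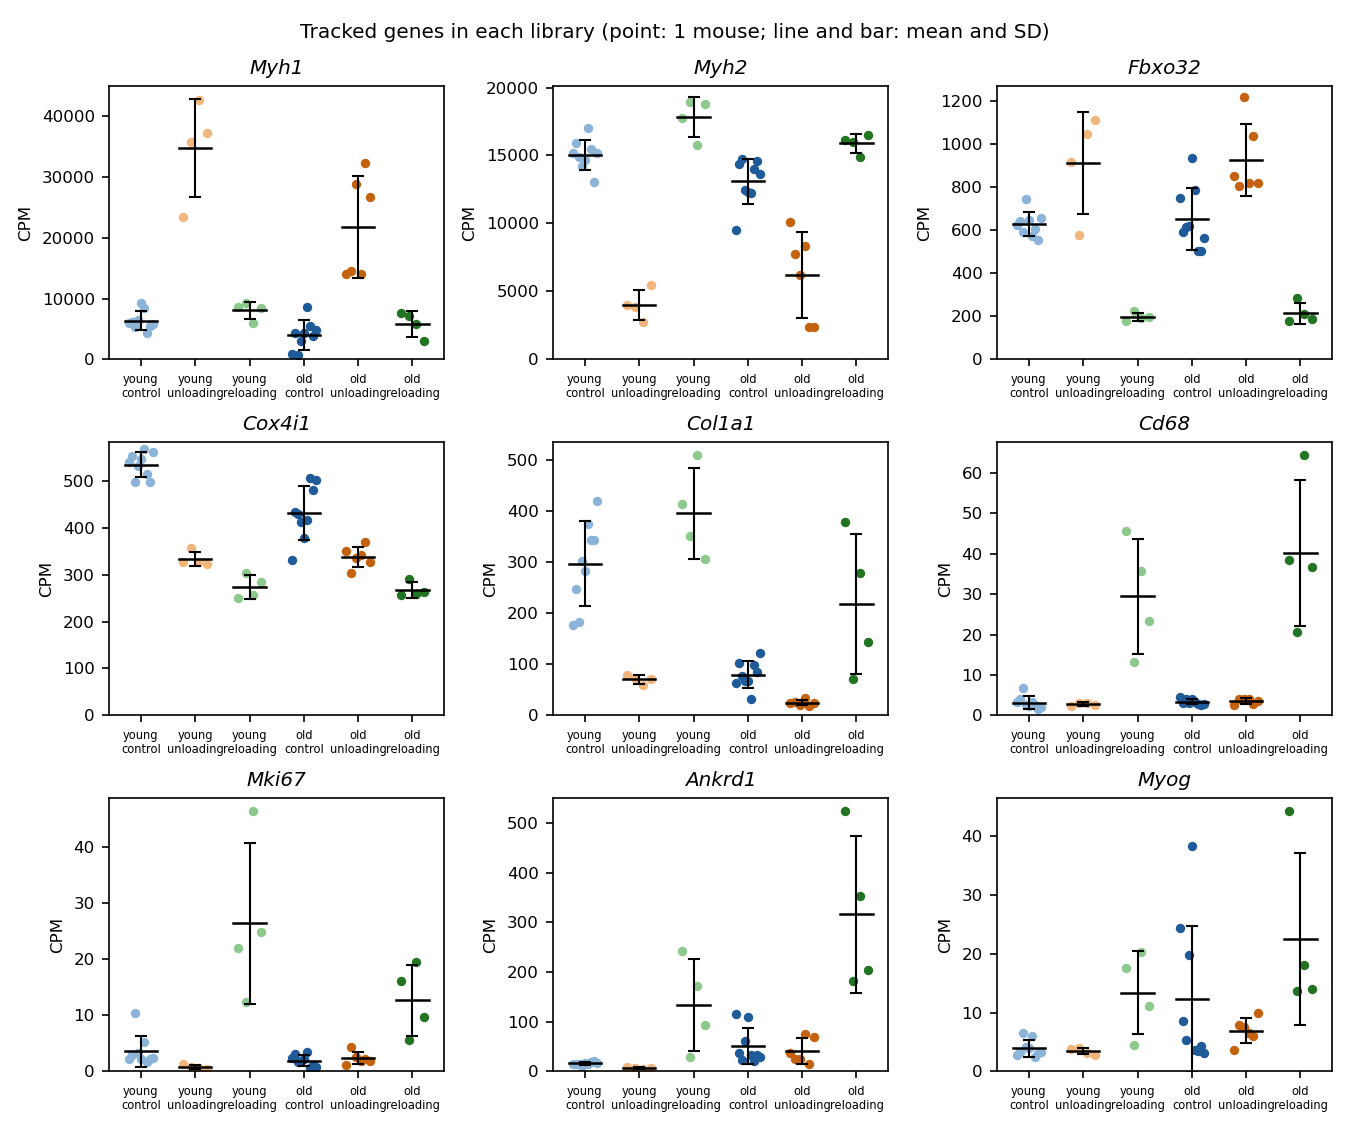
CPM of 9 genes in each library by group, with the mean and SD as a bar; the vertical axes start at 0. Myh1 averaged 34760 CPM in young unloaded mice and 6396 CPM in young controls, and Cd68 averaged 40.2 CPM in old reloaded mice and 3.39 CPM in old controls.

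How far the reloaded muscle stood from control muscle was read in young mice from 4 against 9 animals. Mybph rose by 4.80 ± 0.56, Cd68 by 3.21 ± 0.26, Csrp3 by 3.08 ± 0.27 and Ankrd1 by 3.05 ± 0.42. Chac1 fell by 2.91 ± 0.59, the clock transcription factor gene Arntl by 2.51 ± 0.33 and Snai3 by 2.22 ± 0.27; the transcript BC048679 fell by 3.16 ± 0.27. Ppargc1a fell by 1.87 ± 0.44, Cox4i1, a cytochrome oxidase subunit, by 0.97 ± 0.08 from 534.1 ± 26.1 to 273.7 ± 24.8 CPM, and Fbxo32 by 1.66 ± 0.16. The values of Myh1 (0.33 ± 0.36, adjusted p = 0.467), Myh2 (0.24 ± 0.22, adjusted p = 0.37) and Col1a1 (0.41 ± 0.28, adjusted p = 0.222) were not called. Alb, at 3.03 ± 1.12, lost its call without young reloading replicate 1 (adjusted p = 0.238).

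In these young mice 78 of 79 oxidative phosphorylation genes fell (78 adjusted over the list alone, camera adjusted p = 4.06e-63; adjusted p = 0.0603 with an estimated correlation). Cox8b fell by 1.58 ± 0.10. Fatty acid oxidation genes fell in 23 of 24 cases (24 adjusted over the list alone, camera adjusted p = 2.84e-26, adjusted p = 0.0613 with an estimated correlation). Lpl, the lipoprotein lipase gene, fell by 1.91 ± 0.14. All 19 genes of the citric acid cycle fell (19 adjusted over the list alone, camera adjusted p = 2.56e-23, adjusted p = 0.0603 with an estimated correlation). Mpc1 fell by 1.01 ± 0.07. Of 21 autophagy genes 11 fell and 1 rose (11 and 1 adjusted over the list alone), Lamp1 by 0.54 ± 0.04, a call that held with an estimated correlation (camera adjusted p = 4.37e-05, then 0.00589). Of 34 cell cycle genes 31 rose (31 adjusted over the list alone, camera adjusted p = 2.53e-14; adjusted p = 0.144 with an estimated correlation). Mcm6 rose by 1.82 ± 0.12. Of 23 macrophage genes 18 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 0.000222; adjusted p = 0.607 with an estimated correlation). The comparison called 7460 genes, 4022 higher and 3438 lower, with 1077 changed at least 2-fold.

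In old mice (4 reloaded, 9 controls) Mybph rose by 4.36 ± 0.51, Cd68 by 3.56 ± 0.26, Tnc by 3.26 ± 0.38 and Postn by 3.24 ± 0.35, while Dkk2 fell by 3.69 ± 0.29, the water channel gene Aqp4 fell by 2.89 ± 0.39, BC048679 by 2.79 ± 0.26 and Klhl33 by 2.73 ± 0.28. Col1a1 rose by 1.46 ± 0.27 and Col3a1 by 2.27 ± 0.28. In old reloading replicate 2, the library with the highest Alb, both lay within the range of old controls. Col1a1 was 71.7 CPM there (31.2 to 122.6 in controls, 144.5 to 377.8 in the other reloaded libraries). Col3a1 was 228.9 CPM (78.0 to 233.9 in controls, 681.9 to 1449 in the other reloaded libraries). Apob and Alb had the highest values among called genes with a mean of at least 8 CPM, leaving out predicted genes (10.08 ± 1.43 and 10.02 ± 1.40). The call of Apob ended without the 6 libraries above 20 CPM of Alb (adjusted p = 0.051). Of 79 oxidative phosphorylation genes 74 fell (76 adjusted over the list alone, camera adjusted p = 1.06e-45; adjusted p = 0.141 with an estimated correlation). Cox8b fell by 1.26 ± 0.09. All 24 genes of fatty acid oxidation fell (24 adjusted over the list alone, camera adjusted p = 3.1e-29, adjusted p = 0.0882 with an estimated correlation). Lpl fell by 1.52 ± 0.14. Of 23 macrophage genes 20 rose (20 adjusted over the list alone, camera adjusted p = 7.25e-11; adjusted p = 0.249 with an estimated correlation). The chemokine receptor gene Ccr2 rose by 2.41 ± 0.30. Of 79 cytosolic ribosomal protein genes 73 rose (74 adjusted over the list alone, camera adjusted p = 6.99e-32; adjusted p = 0.202 with an estimated correlation). Rps28 rose by 1.12 ± 0.08. Of 6447 genes called, 3279 were higher and 3168 lower, and 1168 changed at least 2-fold.

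The distance from control after reloading differed between the ages in 724 genes, 349 with a more positive and 375 with a more negative change in old mice. Higher and lower refer here to that difference in change, not to levels. Of 31 named calls 8 held in every alternative run. The first by adjusted p were Lrrc30 (1.40 ± 0.19, adjusted p = 0.000157), the cyclin G1 gene Ccng1 (0.82 ± 0.11, adjusted p = 0.000157), the exocyst gene Exoc4 (0.54 ± 0.08), Suox (0.86 ± 0.13) and the small heat shock gene Hspb6 (-1.12 ± 0.18). Of 16 circadian genes 5 were lower and 2 higher in this test (9 and 2 adjusted over the list alone, camera adjusted p = 8.22e-05; adjusted p = 0.532 with an estimated correlation). Ciart had a value of -2.43 ± 0.47 and Per1 had -1.79 ± 0.35, and both gene calls ended without the 6 libraries above 20 CPM of Alb (adjusted p = 0.0743 and 0.119). Of 79 oxidative phosphorylation genes 8 were higher (14 adjusted over the list alone, camera adjusted p = 4.6e-14; adjusted p = 0.749 with an estimated correlation). Ndufb6 had a value of 0.42 ± 0.09. Of 34 matrix genes 3 were higher and 1 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.000697; adjusted p = 0.749 with an estimated correlation). Cthrc1 had a value of 2.11 ± 0.58 and Postn had 1.87 ± 0.52. The call of Ndufb6 ended without those 6 libraries (adjusted p = 0.17) and those of Cthrc1 and Postn without young reloading replicate 2 (adjusted p = 0.0768 and 0.0909). The count was 141 without the 6 libraries, 288 without young reloading replicate 2, 379 without old reloading replicate 4 and 1182 without young reloading replicate 1.

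Age was read in 9 old against 9 young controls. The stress gene Gadd45a rose by 3.11 ± 0.56, Aif1l by 2.92 ± 0.50, the calcium release channel gene Ryr3 by 2.47 ± 0.32, the G protein gene Gnal by 2.39 ± 0.19 and the transcription factor gene Runx1 by 1.92 ± 0.40. Myh4 fell by 3.79 ± 0.82, from 1885 ± 2428 to 136.4 ± 232.6 CPM, Mybpc2 fell by 3.07 ± 0.54, the mitochondrial leucyl-tRNA synthetase gene Lars2 by 2.02 ± 0.36 and Col1a1 by 1.90 ± 0.23 from 296.6 ± 83.5 to 79.5 ± 26.7 CPM. Myh7 rose by 0.39 ± 0.11, the cell cycle inhibitor gene Cdkn1a by 1.57 ± 0.31, Myog by 1.65 ± 0.41 and Ankrd1 by 1.67 ± 0.36, while the growth factor gene Igf1 fell by 0.78 ± 0.13. Fbxo32 had a value of 0.06 ± 0.12 (adjusted p = 0.768). The rises of Gadd45a, Runx1 and Myog came from part of the old controls, since in replicates 7 to 9 Gadd45a (3.84 to 5.77 CPM), Runx1 (9.2 to 15.4 CPM) and Myog (3.06 to 4.28 CPM) were no higher than in the highest young control (7.08, 17.2 and 6.46 CPM).

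Of 18 genes of the neuromuscular junction and denervation list 14 rose and 4 were not called in old controls (15 rose adjusted over the list alone, camera adjusted p = 5.44e-07; adjusted p = 0.213 with an estimated correlation). The list mean followed the replicate numbers of the 9 old controls: replicates 1 to 6 (3.91 to 5.56) lay above the highest young control (3.78), and replicates 7 to 9 (3.41 to 3.59) lay within the range of the young controls. Chrng, the fetal acetylcholine receptor subunit, rose by 3.65 ± 0.71. Of 13 fast fibre genes 10 fell (12 adjusted over the list alone, camera adjusted p = 7.08e-09; adjusted p = 0.134 with an estimated correlation). Tnni2 fell by 0.42 ± 0.08. The young controls behind this comparison stood apart from each other, since Myh4 was 3807, 5952 and 5296 CPM in replicates 4, 7 and 9 and 73.2 to 984 CPM in the other 6, and Actn3, Pvalb, Casq1 and Mybpc2 went with it (r = 0.971, exact two-sided permutation p = 5.51e-06, n = 9). Tissue of a neighbouring fast muscle in these libraries was not excluded. Of 12 slow fibre genes 7 rose (8 adjusted over the list alone, camera adjusted p = 0.000121; adjusted p = 0.317 with an estimated correlation). Casq2 rose by 0.58 ± 0.10. Of 34 collagen and matrix genes 23 fell (25 adjusted over the list alone, camera adjusted p = 2.62e-20; adjusted p = 0.168 with an estimated correlation). Col6a1 fell by 0.93 ± 0.10 and Sparc by 1.04 ± 0.12. Of 11 tendon genes 8 fell (10 adjusted over the list alone, camera adjusted p = 9.68e-09; adjusted p = 0.168 with an estimated correlation). Cilp2 fell by 1.83 ± 0.24. Of 79 oxidative phosphorylation genes 61 fell (64 adjusted over the list alone, camera adjusted p = 4.51e-26, adjusted p = 0.226 with an estimated correlation). The lower values of the tracked mitochondrial genes Cox4i1 and Cs were mainly those of old control replicates 1 to 6. Cox4i1 was 330.3 to 432.8 CPM there, 481 to 505.9 CPM in replicates 7 to 9 and 496.3 to 566.5 CPM in young controls. Cs was 592.3 to 764.9, 756.7 to 830.4 and 754.3 to 895.6 CPM in the same order. The list as a whole was not compared by replicate number. Of 18 genes of glycolysis and glycogen 12 fell (15 adjusted over the list alone, camera adjusted p = 2.05e-12; adjusted p = 0.134 with an estimated correlation). Phkg1 fell by 0.88 ± 0.11. The comparison called 3561 genes, 1824 higher and 1737 lower, with 328 changed at least 2-fold.

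After unloading, 6 old and 4 young mice differed in 1474 genes, 698 higher and 776 lower in old mice, and 30 of 64 named calls held in every alternative run. Ankrd1 was higher in old mice by 2.52 ± 0.54, Gnal by 2.45 ± 0.27, Ryr3 by 2.09 ± 0.47 and Ddit4 by 1.69 ± 0.32. Aqp4 was lower (-1.75 ± 0.33). Mybpc2 had the lowest value among called genes with a mean of at least 8 CPM, leaving out predicted genes (-2.26 ± 0.68). This call ended without young unloading replicate 2 (adjusted p = 0.0825). Of 34 collagen and matrix genes 13 were lower (19 adjusted over the list alone, camera adjusted p = 2.39e-10; adjusted p = 0.383 with an estimated correlation). Col15a1 had a value of -1.05 ± 0.16. Of 18 antioxidant genes 6 were higher (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0139; adjusted p = 0.464 with an estimated correlation). Nqo1, a quinone reductase, had a value of 1.06 ± 0.17. The count was 789 without young unloading replicate 2 and 932 without the 6 libraries above 20 CPM of Alb.

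After reloading, 4 old and 4 young mice differed in 2960 genes, 1507 higher and 1453 lower in old mice, and 23 of 66 named calls held in every alternative run. Ryr3 was higher in old mice by 2.79 ± 0.46, Gnal by 2.78 ± 0.28 and Ndrg4 by 2.30 ± 0.40, and Mylk4, a kinase gene of muscle (-2.98 ± 0.51), and Nos1, the neuronal nitric oxide synthase gene (-2.97 ± 0.47), were lower, as was Aqp4 (-2.44 ± 0.43). Alb and Apob (4.14 ± 1.41 and 4.07 ± 1.29) and the fast fibre genes Myh4 (-4.63 ± 1.28), Mybpc2 (-3.90 ± 0.86) and Pvalb (-2.65 ± 0.72) lost their calls without the 6 libraries above 20 CPM of Alb (adjusted p = 0.864, 0.927, 0.156, 0.0655 and 0.137). Of 12 endothelial genes 6 were lower (8 adjusted over the list alone, camera adjusted p = 4.72e-07; adjusted p = 0.365 with an estimated correlation). Tie1 had a value of -0.83 ± 0.11 and the endothelial cadherin gene Cdh5 had -0.83 ± 0.12. Of 79 cytosolic ribosomal protein genes 59 were higher (70 adjusted over the list alone, camera adjusted p = 4.95e-29; adjusted p = 0.365 with an estimated correlation). Rps28 had a value of 0.66 ± 0.10. The count was 793 without the 6 libraries and 695 when only the 8 reloaded libraries were fitted.

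**Figure D5:**
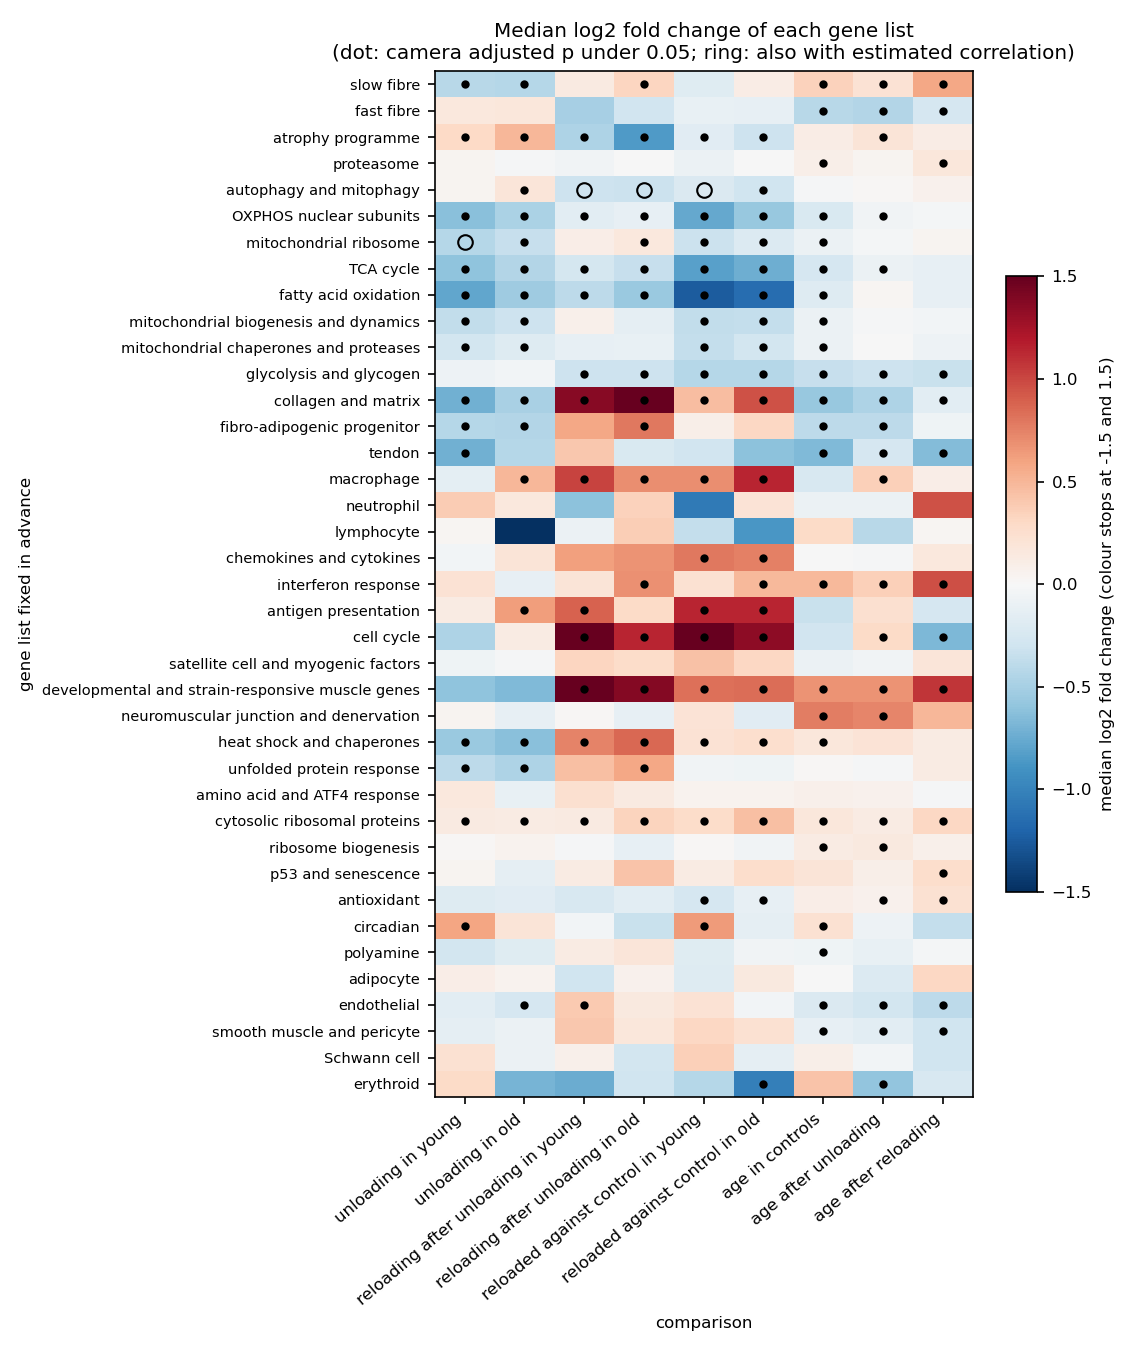
Colour gives the median log2 fold change of each of 39 gene lists in 9 comparisons; a dot marks a camera adjusted p under 0.05 and a ring one that also held with an estimated correlation. Rings stand for the mitochondrial ribosome in unloaded young muscle (median -0.43) and for autophagy and mitophagy in reloaded muscle (median -0.31 in young and -0.32 in old mice against unloading).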

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

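The tests of the liver, fast muscle and denervation patterns were chosen after those results were seen, except the epithelial test, which was written before its values; the regroupings of libraries were fixed before the data were examined.

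Liver genes stood out in old reloading replicate 2, with 1743 CPM of Alb (59593 reads), 397 CPM of Apob, and lower levels in 5 other libraries. Of a list of 22 liver genes, of which 2 averaged at least 1 CPM in control muscle and 0 were on another list, 22 were measured and 100% had their highest value of all libraries there, and Apob kept a nearly fixed ratio to Alb (SD of log2 ratio 0.473) over 15 libraries whose Alb spanned 448.1-fold. Expression by the reloaded old muscle itself is argued against by Alb exceeding the highest old control (1.71 CPM) in only 3 of the 4 old reloaded libraries, with 0.195 CPM in the remaining library. A candidate source is RNA from liver that entered these libraries, as a hypothesis from the marker list (value 100). How such RNA came in stays open.

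Myh4, the fastest myosin heavy chain gene, spanned 81.3-fold over the 9 young controls. Over the same libraries Myh1 spanned 2.1-fold (4415 to 9265 CPM) and Myh2 1.31-fold (13020 to 17020 CPM), while Myh4 ran from 73.2 to 5952 CPM. These spans cannot decide whether Myh4 shared reads with its neighbours, since small fold changes of such abundant genes could hide them. Other fast fibre genes of modest level (Actn3, Pvalb, Casq1 and Mybpc2) went with Myh4 (r = 0.971, exact two-sided permutation p = 5.51e-06; rho 0.983, exact p = 4.96e-05; r = 0.943 without the 2 libraries farthest from the median; 1 relation computed, n = 9). Reads shared among heavy chain genes would not by themselves make these other genes go with Myh4. Tissue of a neighbouring fast muscle may account for that relation. It cannot be told apart from soleus muscles that differ in their own fast fibres, because both predict the same relation.

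The neuromuscular junction and denervation list varied widely among the old controls (4.26 ± 0.77, against 3.46 ± 0.14 in young controls), with replicates 1 to 6 at 3.91 to 5.56 and replicates 7 to 9 at 3.41 to 3.59. Depth is argued against by totals that differed only 1.15-fold. Epithelial cells are argued against by 14.3% of the measured epithelial genes (1 of 7) peaking in the old control with the highest Krt18 (Epcam 0 CPM, Krt18 38.6 CPM). A batch shared by the controls numbered 7 to 9 of both ages stays open. Between controls 7 to 9 and 1 to 6 edgeR called 0 genes in young mice (1324 at an unadjusted p under 0.05) and 412 in old mice. No other tool was run, and so few libraries can miss a shared shift. On the first principal component (31.38% of the variance of 2000 genes), replicates 7 to 9 lay below replicates 1 to 6 at both ages. The values were -21.32 to -17.43 and -15 to 5.31 in young controls, and -20.68 to -18.11 and -14.58 to -8.23 in old controls. The list mean was higher in old than in young unloaded mice (6 of 6 above the highest young mouse; exact two-sided permutation p = 0.00952, Benjamini-Hochberg p = 0.0143 over 3 tests), in controls (6 of 9; exact p = 0.00271, Benjamini-Hochberg p = 0.00813) and after reloading (4 of 4; exact p = 0.0286, Benjamini-Hochberg p = 0.0286). These tests compare the ages and leave open why old controls differed from each other. A batch of old controls alone was not tested.

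Of 162 groups of values, 10 held a library far from the others, where chance gives about 1 in 20 groups such a value (8.1 expected). Young reloading replicate 2 had 32.3 M reads, below the next library at 33.9 M reads. In old reloading replicate 1 the read column made up 67.3% of the total implied by the RPKM column, above the next at 66.8%. Myh2 was 9510 CPM in old control replicate 1 (next 12200). Myh4 was 752 CPM in old control replicate 8 (next 121). Cox4i1 was 356 CPM in young unloading replicate 2 (next 327). Col1a1 was 31.2 CPM in old control replicate 6 (next 62.7), and Col3a1 was 78 CPM there (next 174). Col3a1 was 909 CPM in young control replicate 6 (next 545), and Myh3 was 212 CPM there (next 48.9). Ccl2 was 0.176 CPM in old control replicate 7 (next 0.445).

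The response to reloading differed between the ages in 117 genes by a test of the difference itself. It is given here as the log2 change of old mice minus that of young mice, which is not a difference in level. Among the named genes the values were -1.08 for Ldhd, 1.23 for Acly, 0.78 for Myh14, 0.42 for Hook3, 0.78 for Suox, 1.06 for Xirp2, -0.94 for Fgf1, -0.58 for Plpp3, 0.34 for Psmd6 and -3.45 for Aurkb. Of these 10 calls only those of Ldhd, Myh14 and Suox (3) held in every alternative run, and in overlapping sets 6 ended under another choice of libraries, low-count filter or replicate block, 2 on leaving out 1 library, 4 without the 6 libraries above 20 CPM of Alb and 2 with controls 1 to 6 alone. For the distance from control after reloading 724 genes differed: Lrrc30 (1.40), Ccng1 (0.82), Exoc4 (0.54), Suox (0.86), Hspb6 (-1.12), Aamdc (0.60), Gprc5b (-1.08) and Gpr146 (-0.61) had the smallest adjusted p, and these 8 of 31 named calls held in every alternative run. The other calls, including those given next, each ended in at least 1 alternative: in overlapping sets, 18 on leaving out 1 library, 11 under another choice of libraries, low-count filter, transcript or replicate block, 19 without the 6 libraries above 20 CPM of Alb and 4 with controls 1 to 6 alone. The mitochondrial genes Ndufb6 (0.42), Ndufa1 (0.41), Ndufs6 (0.33), Cox6b1 (0.34), Mrps12 (0.35), Mrpl13 (0.35), Mrps36 (0.45), Mrps5 (0.31) and Mpc1 (0.50) had a more positive change from control in old mice. So did the matrix genes Cthrc1 (2.11), Postn (1.87) and Fn1 (0.81), the ribosomal protein gene Rps28 (0.46) and the antioxidant genes Prdx5 (0.37) and Gpx4 (0.29). The clock genes Ciart (-2.43), Per1 (-1.79), Per2 (-1.66) and Hlf (-1.39), the endothelial genes Tie1 (-0.52) and Cdh5 (-0.56) and the Schwann cell gene Egr2 (-1.24) had a more negative change in old mice. Such differences can come from the controls as well as from the reloaded muscle, and these were not separated. The tracked mitochondrial gene Cox4i1 averaged 534.1 CPM in young and 431.7 CPM in old controls, and 273.7 and 267.4 CPM after reloading. Cs was lower in old mice both in controls (825.4 and 715.5 CPM) and after reloading (483.1 and 427.7 CPM).

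Regrouping the libraries gave no other grouping with as many calls as the real one, within an age or for age within a treatment. The distinct groupings, the real one included, were 30 for reloading after unloading in young mice, 32 for age after reloading and 77 to 89 for the others. These few groupings argue against chance as the source of the counts without excluding it. The real count and the highest other were 6130 and 1 for unloading in young mice, 6425 and 88 in old mice, 7204 and 642 for reloading after unloading in young mice, 7717 and 2671 in old mice, 7460 and 2895 for reloaded against control in young mice, 6447 and 957 in old mice, 3561 and 1519 for age in controls, 1474 and 272 after unloading and 2960 and 409 after reloading. For the differences between the ages in a response they were 117 and 216 for reloading and 724 and 1497 for reloaded against control, so that 2 of 90 groupings, the real one included, called as many genes. That share is under the limit of 1 in 20 set before the data were examined. These regroupings mixed the ages within each treatment, however, and so also broke up age differences common to all treatments. The share alone therefore cannot decide whether the responses differed between the ages. In both comparisons the grouping with more calls kept all 4 young and all 4 old reloaded libraries in their age groups and mixed only controls and unloaded mice, so it held the age difference after reloading and was not a grouping by chance alone. Another that kept them called 8 and 175 genes. For unloading the real grouping called 0 genes with edgeR (1487 at an unadjusted p under 0.05; 8 by DESeq2) and the highest other 365, and with a real count of 0 there is nothing for the regrouping to test (90 of 90 groupings necessarily called as many). Groupings with more calls than the real one point to a structure of the samples. For the 2 comparisons with reloaded mice the kept age groups are part of it, and what else contributes, or lies behind the count for unloading, was not tested.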

How the results depend on the processing

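The omission of the 6 libraries with Alb above 20 CPM and the restriction to controls 1 to 6 were added after the data were seen; all other alternatives were chosen before the data were examined. The counts for unloading, reloading and reloaded against control within an age and for age in controls stayed within 1.5 times of their reported value in every alternative, and leaving out 1 library gave 5069 to 6095 for unloading in young mice, 5897 to 6561 in old mice, 6412 to 7258 for reloading in young mice, 6912 to 7514 in old mice, 6588 to 7470 for reloaded against control in young mice, 5476 to 6506 in old mice and 3048 to 3726 for age in controls. Of the named genes with 1 library left out, pooled over all 12 comparisons, 12810 results kept their side of the threshold, 22 became called and 299 lost the call. Direction was checked only where a gene was called with or without the library. At most 5 named calls ended so in any of these 7 comparisons, against 30 for age after unloading, 17 for age after reloading and 18 for reloaded against control by age. The cause was not tested for the changes that follow, except that fewer libraries leave fewer residual degrees of freedom; without the 6 libraries each reloading group keeps 2.

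For unloading by age (0 reported with edgeR, 1487 at an unadjusted p under 0.05) a replicate block for the mouse number, which does not pair the libraries, gave 3, fitting only the libraries of the contrast 5, the DESeq2 Wald test 8 and controls 1 to 6 alone 59; leaving out 1 library gave 0 to 2 (2 without young control replicate 7, 1 without old unloading replicate 4). For reloading by age (117) only the libraries of the contrast gave 17, DESeq2 399 and the omission of the 6 libraries 55; leaving out 1 gave 47 to 258, namely 57 and 65 without young unloading replicates 2 and 4, 258 and 59 without young reloading replicates 1 and 3, 77 and 210 without old unloading replicates 3 and 6, and 187, 181 and 47 without old reloading replicates 1, 3 and 4. For reloaded against control by age (724) the same settings gave 367, 1207 and 141, and leaving out 1 library 288 to 1182 (288 without young reloading replicate 2, 1182 without replicate 1, 379 without old reloading replicate 4). Age after unloading (1474) gave 932 without the 6 libraries and 789 (without young unloading replicate 2) to 1510. Age after reloading (2960) gave 695 with only its own libraries, 793 without the 6 and 1974 to 3223 with 1 left out.

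With an estimated correlation 1 list stayed called for unloading in young mice (15 reported), 1 for reloading in young (14) and 1 in old mice (17) and 1 for reloaded against control in young mice (19), and 0 for unloading in old mice (17), reloaded against control in old mice (20), the differences between the ages (14, 8 and 12) and age in controls (23), after unloading (20) and after reloading (14). Without the 6 libraries Alb for reloaded against control in young mice was -0.10 (adjusted p = 0.952) and Trf for age after reloading -0.056 (adjusted p = 0.935), both turned, as were the oxidative phosphorylation list for reloading by age (adjusted p = 0.017) and the collagen and matrix list for age after reloading (adjusted p = 0.886). Pseudocount alternatives did not apply to counts. Simulated changes of 1.5-fold were found in 49% of genes for unloading by age and 30% for reloading by age. These simulations had 4 to 9 mice per group and 32.0 to 37.9 M reads, and neither number was varied. They gave genes of like level the same spread, so real genes that vary more may be found less often.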

Other observations

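The comparisons of genes, the gene lists and the choice of transcript in this part were planned; which lists are described, the tests of the read column and the omission of 6 libraries were chosen after the data were seen. Clock genes differed in the reloaded young muscle, where 10 of 16 circadian genes rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.035; adjusted p = 0.526 with an estimated correlation, and 0.156 without the 6 libraries above 20 CPM of Alb). Bhlhe41, a repressor of the clock, rose there by 1.35 ± 0.17, Per1 by 1.67 ± 0.24, Per2 by 1.62 ± 0.24 and Ciart by 1.74 ± 0.31, while Arntl, a driver of the clock, fell by 2.51 ± 0.33 (n = 4 and 9). In old mice Arntl fell by 1.05 ± 0.30, and 1 circadian gene rose and 2 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.779, n = 4 and 9). Old controls had higher Per1 (1.25 ± 0.20) and Cry2 (0.54 ± 0.09) than young controls. Of 16 circadian genes 4 were called higher there (4 adjusted over the list alone, camera adjusted p = 0.00706, adjusted p = 0.317 with an estimated correlation). The hour of collection was not part of the sample information used here. For every circadian result given above, a difference in that hour between groups cannot be told apart from unloading, reloading or age.

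Interferon response genes were higher with age: 8 of 22 in controls (11 adjusted over the list alone), with Irf7 at 1.55 ± 0.36 and Ifit1 at 1.41 ± 0.36 (camera adjusted p = 0.00277; adjusted p = 0.588 with an estimated correlation, n = 9 and 9), and 11 of 22 after reloading (15 adjusted over the list alone; camera adjusted p = 6.45e-07; adjusted p = 0.511 with an estimated correlation, n = 4 and 4). The call of Irf7 in controls ended with the most abundant transcript in place of the sum (adjusted p = 0.0884). The 9 erythroid genes, among them the alpha globin gene Hba-a1 (-0.59 ± 0.24), which shares reads with its copy, fell in 9 of 9 cases in unloaded old muscle (9 adjusted over the list alone), although the list was not called (camera adjusted p = 0.127), and in young mice 0 of 9 were called (0 adjusted over the list alone; camera adjusted p = 0.457). Of 13 genes of the p53 and senescence list 5 rose and 2 fell with age in controls (7 and 2 adjusted over the list alone; camera adjusted p = 0.201).

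The read column made up 65.3% of the total implied by the RPKM column in young controls, 62.3% after unloading and 65.6% after reloading, and 65.3%, 62.5% and 66.9% in old mice. Unloaded mice lay below controls at both ages (exact two-sided permutation p = 0.0014 in young and 2e-04 in old mice; Benjamini-Hochberg p = 0.00788 and 0.0045 over 45 tests).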
